A study of Kineococcus radiotolerans with 2 samples.

How the data were processed

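RNA of *Kineococcus radiotolerans* strain ATCC BAA-149, a radiation-resistant actinobacterium, was sequenced in 2 libraries, 1 of wild-type cells and 1 of cells called radiation induced. Samples were grouped by their titles and genotype labels alone. Both samples carry the same text on gamma irradiation (0.225 kGy/h for 20 h from a cobalt source, then 3 h of incubation), and it was read here as describing the radiation-induced sample, since only the titles and genotype labels separate the samples. Per the labels' protocols, total RNA was isolated with Trizol, ribosomal RNA was reduced with the MICROBExpress kit, and the cDNA libraries were sequenced as paired reads of 100 nt on a HiSeq instrument. The labels do not say whether strand was kept.

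The deposited values are RPKM (reads per kilobase of gene, scaled to a fixed number of mapped reads), as the file headers name them, with 1 value per gene and library. TopHat is the only program named in the submitters' processing notes, without a version. The genome build, the annotation version, the program that made the RPKM values, and its handling of strand and of reads with several matches are not given in the sources used here. The files also give each gene's locus tag, product name, strand, start and end, protein length and COG class. For 2584 of the 2584 genes the span from start to end equalled the coding length implied by the protein length, so the lengths are coding lengths. The files name no replicon, and the coordinates start again at locus Krad_4514, so positions are given as the files give them, without a replicon or build. Each library lists only genes above 1 RPKM, with a lowest value of 1.00 in the wild-type and 1.01 in the irradiated library. Genes missing from both libraries were not analysed here.

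Depth is unknown. The RPKM values are not whole multiples of 1 read over gene length, so read numbers were not recovered and no counting interval is given. The RPKM values multiplied by coding length summed to 49.7% of the fixed number that RPKM is scaled to in the wild-type library and 54.0% in the irradiated library; where the remaining reads went was not analysed here.

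For each of the 2545 genes listed in both libraries the log2 ratio of irradiated over wild type was computed after adding a pseudocount of 1 RPKM, so the ratios of low genes are understated. A gene entered the comparison when the larger of its 2 values was at or above the 25th percentile of all listed values (17.4 RPKM), which left 2059 genes. The 39 genes listed in only 1 library have no ratio and are described separately. The values were used as deposited, without further scaling. With 1 library per group there is no estimate of the spread between cultures, so no p-value was computed and no gene is called changed; genes at least 2-fold apart were counted in each direction. Folds are given on the scale of RPKM plus the pseudocount.

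Before the data were examined, 28 gene lists were fixed by patterns on gene symbols and product names. The patterns also caught 17 genes that do not belong to their list, such as a leucine synthesis enzyme in the citric acid cycle list; these were removed by reading the product names, after the values had been seen. Lists with at least 5 members that passed the filter (23 lists) were described by their median log2 ratio and by that median's percentile among 10000 random lists of the same size, drawn from genes in the same decile of mean expression. The percentile describes these 2 libraries and is not a test of the conditions. COG classes, taken from the files and not fixed in advance, were described in the same way. Pearson and Spearman correlations between the libraries are across genes, which are not independent replicates.

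The rule for naming genes was also fixed before the data were examined. It took the 12 genes with the highest and the 12 with the lowest log2 ratio among genes that have a product name and whose larger value reached the median of all listed values (46.2 RPKM), the 2 members of each list with the largest absolute log2 ratio at that level, 11 genes fixed by name (recA, lexA, uvrA, catalase, superoxide dismutase, ahpC, dnaK, groL, ku, gyrB and rpoB), and the 5 highest values of each library. It gave 81 genes. No product name matched lexA or ku. Genes of unknown function were counted rather than named. Other members of the lists and neighbours of named genes are also given where they describe a group; these were chosen after their values were seen.

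The alternatives were pseudocounts of 0.1 and 10 RPKM, no filter, a filter at the median, centring on the median log2 ratio, scaling by the upper quartile, by the total and by the total without the 50 most abundant genes, a 4-fold threshold, random lists drawn without matching, and the mean of a list in place of its median. Added after seeing the data were entering genes missing from 1 library at 0, keeping the 17 wrong matches, matching random lists on protein length as well, and leaving out of the regulator list the genes it shares with the two-component list. Runs of neighbouring genes were also counted after centring, added in the same way.

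The calculation was tested on simulated data for the irradiated against wild-type comparison, with 2545 genes and an assumed noise of 0.3 (SD, log2) in each library. That noise was not estimated from these libraries, so the simulated shares do not say how many observed genes differ through noise. Every simulated irradiated value was also lowered by 0.3 on the log2 scale. Lower genes therefore reached 2-fold more easily than higher genes. Of genes simulated with a log2 change of 2, 93.3% were at least 2-fold higher, and with a change of -2, 100% were at least 2-fold lower; for 1.5 and -1.5 the shares were 65.2% and 100%, and 4.96% of the 1774 unchanged genes were at least 2-fold apart. A simulated raised list of 12 genes reached percentile 100, and 7% of 200 unchanged lists fell outside the central 95% of random lists. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.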

Results

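The transcriptome of *Kineococcus radiotolerans* was measured in 1 library of wild-type cells and 1 library of cells labelled as radiation induced. *K. radiotolerans* is an orange-pigmented actinobacterium that survives high doses of ionizing radiation. The irradiation protocol gives 0.225 kGy/h of gamma radiation for 20 h, 4.5 kGy in all, followed by 3 h of incubation before RNA was taken. The wild-type library listed 2570 genes and the irradiated library 2559, with 2545 genes in both. Median expression was 50.9 RPKM in the wild-type and 41.4 RPKM in the irradiated library. The series addresses which genes differ in expression between irradiated and wild-type cells. There were no replicates, so no difference below has a check against the spread between cultures.

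The highest values in the wild-type library belonged to ribosomal protein L31 (Krad_1256, 69305 RPKM), translation initiation factor IF-1 (Krad_0711, 61343 RPKM), ribosomal protein S12 (Krad_0682, 36869 RPKM), Krad_0822, a protein of unknown function with 44 amino acids (33798 RPKM), and ribosomal protein L30 (Krad_0706, 33694 RPKM). In the irradiated library the order was Krad_0822 (80875 RPKM), Krad_1041 (80292 RPKM), L31 (64236 RPKM), IF-1 (62227 RPKM) and the CsbD family protein Krad_4239 (56403 RPKM). Krad_1041, which encodes 72 amino acids of unknown function, had 8884 RPKM in the wild-type library and was 9.04-fold higher in the irradiated one. The 10 highest genes held 32.4% of the summed RPKM in the wild-type library and 38.9% in the irradiated library.

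Of the 2059 genes that passed the filter, 121 (5.88%) were at least 2-fold higher in the irradiated library, 256 (12.4%) were at least 2-fold lower and 1682 lay within 2-fold. At a 4-fold threshold, 47 genes were higher and 19 lower. The median log2 ratio of all genes was -0.31, and taken relative to that median the 2-fold counts were 194 higher and 121 lower. The balance between higher and lower genes therefore depended on the scaling, with 32.1% of the 2-fold genes higher as deposited and 61.6% higher relative to the median. Genes of unknown function made up 48 of the 121 higher and 101 of the 256 lower genes. Across genes, the libraries correlated with a Pearson r of 0.923 and a Spearman rho of 0.898.

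**Figure D1:**
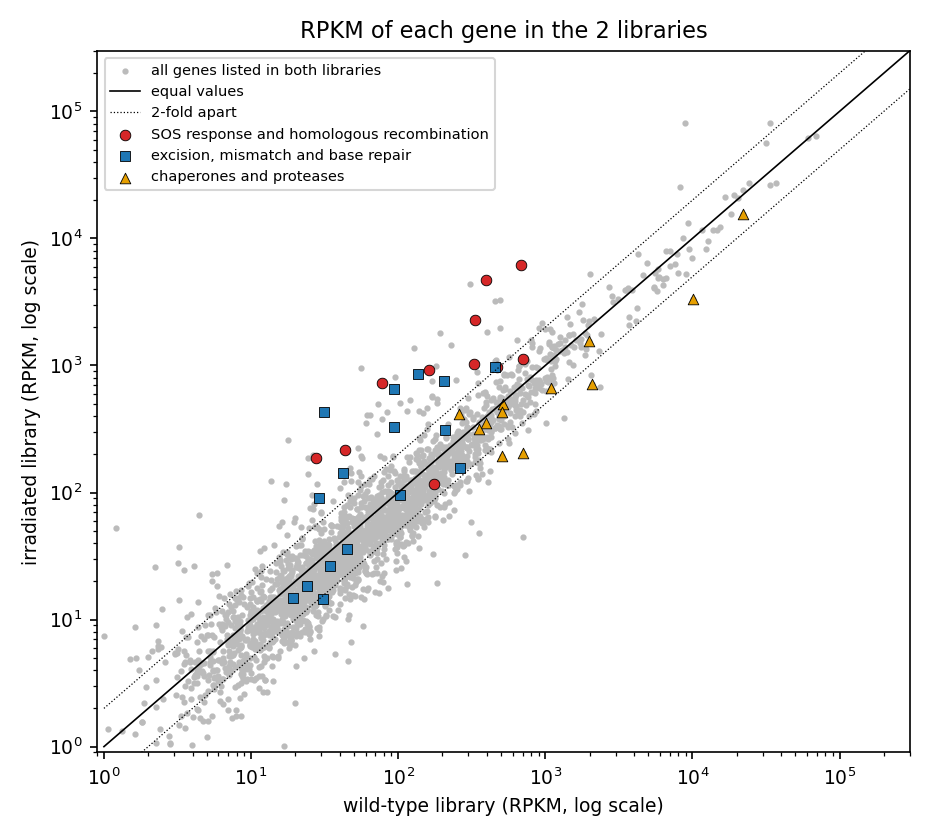
RPKM of each gene in the wild-type library (x axis, log scale) and the irradiated library (y axis, log scale), with members of 3 gene lists marked, a solid line at equal values and dotted lines at 2-fold. Most recombination genes lie above the upper dotted line, with recA at 683 and 6209 RPKM, and 4 chaperone genes lie below the lower one.

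Genes of homologous recombination and the SOS response stood highest in the irradiated library. Of 11 members, 9 were at least 2-fold higher and none was 2-fold lower. The median log2 ratio of the list was 2.52, 2.83 above the median of all genes, at percentile 100 of matched random lists. The gene for RecA (Krad_1492), the recombinase that pairs homologous DNA strands and triggers the SOS response, had 683 RPKM in the wild-type and 6209 RPKM in the irradiated library, 9.08-fold higher. The adjacent gene for RecX (Krad_1493), a regulator of RecA activity, went from 393 to 4671 RPKM, 11.9-fold. RuvA and RuvB, which form the motor that moves Holliday junctions, were 6.84-fold (Krad_3054) and 9.30-fold (Krad_3053) higher. These neighbouring genes overlap, so their reads cannot be fully told apart. The beta and gamma subunits of exodeoxyribonuclease V, which processes DNA ends, were 4.87-fold (Krad_0993) and 6.55-fold (Krad_0992) higher, RadA (Krad_0603) was 5.74-fold higher and RecR (Krad_0465) 3.14-fold higher. RecF (Krad_0004) was at 1.58-fold, and the YqgF resolvase (Krad_3031) was the single member below the median of all genes, with 176 RPKM in the wild-type and 117 RPKM in the irradiated library.

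Excision and base repair genes were divided. Of 16 members, 8 were at least 2-fold higher and 1 was 2-fold lower, or 8 and 0 relative to the median of all genes, with a median log2 ratio of 0.83 at percentile 100. DNA-3-methyladenine glycosylase I (Krad_0999), which removes alkylated bases, had 31.5 RPKM in the wild-type and 429 RPKM in the irradiated library, 13.2-fold higher. All 3 subunits of the UvrABC excinuclease, which cuts out bulky DNA lesions, were higher: UvrA (Krad_2940) 3.44-fold, UvrB (Krad_2942) 6.87-fold and UvrC (Krad_2935) 3.35-fold. The NAD-dependent DNA ligase (Krad_1315) was 6.25-fold and DNA polymerase I (Krad_2951) 3.02-fold higher. The ratios of 7 members were below 0, most of them near the median of all genes, such as formamidopyrimidine-DNA glycosylase (Krad_0294, log2 ratio -0.35, or -0.04 relative to that median). The lowest were 1 of the 2 genes for exodeoxyribonuclease III (Krad_4198, -0.75) and a photolyase-like protein (Krad_3082, -1.03), which belongs to a family that repairs ultraviolet damage. The ATP-dependent DNA ligase Krad_0653, the single listed member of the end-joining list, had 109 RPKM in the wild-type and 112 RPKM in the irradiated library.

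**Figure D2:**
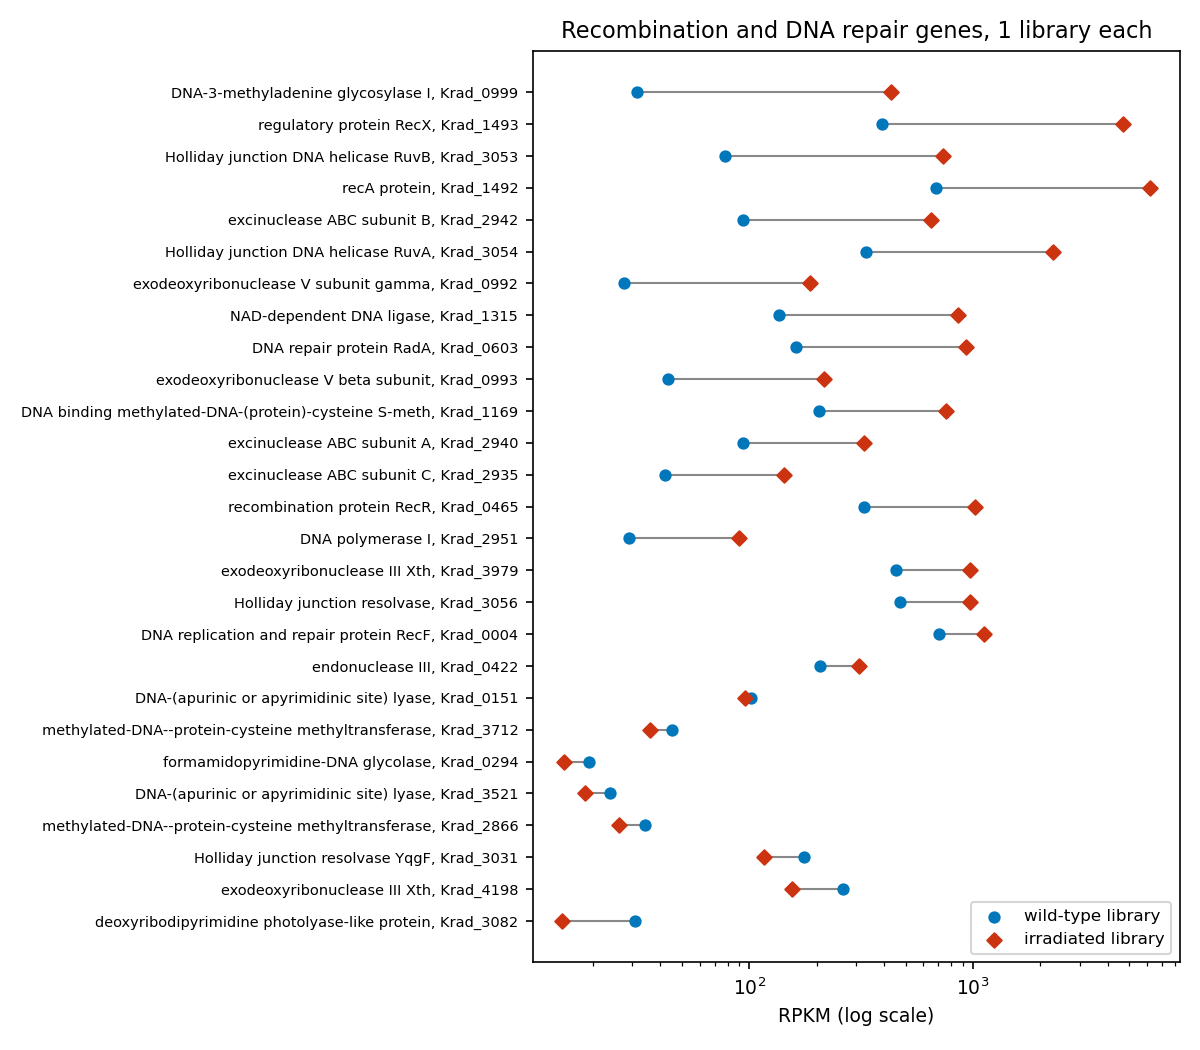
RPKM (x axis, log scale) of the members of the recombination and excision repair lists (y axis, ordered by log2 ratio) in the wild-type library (circles) and the irradiated library (diamonds), 1 library each, joined by a line per gene. The glycosylase Krad_0999 has the highest ratio, 31.5 against 429 RPKM, and the photolyase-like gene Krad_3082 the lowest, 30.9 against 14.6 RPKM.

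Genes of DNA replication also leaned towards the irradiated library. Of 13 members, 4 were at least 2-fold higher and none 2-fold lower, with a median log2 ratio of 0.58 at percentile 99.97. The replicative DNA helicase Krad_4333 went from 24.6 to 139.6 RPKM, 5.50-fold higher, and the gamma and tau subunits of DNA polymerase III (Krad_0466), next to recR, were 3.42-fold higher. The gene for the gyrase B subunit (Krad_0006) was 1.54-fold higher, and that for single-strand binding protein (Krad_4338) had a log2 ratio of -0.43.

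Among the 12 named genes with the highest ratios, 5 belonged to the recombination and excision repair lists. The highest was an ATPase (Krad_2555, positions 4438834 to 4440936 on the plus strand), with 17.9 RPKM in the wild-type and 258 RPKM in the irradiated library, 13.7-fold higher. It lay in a run of 6 neighbouring genes on the same strand, Krad_2551 to Krad_2556, that were all at least 2-fold higher, among them an SMC domain protein (Krad_2553, log2 ratio 2.67) and a metallophosphoesterase (Krad_2554, 1.70). Low values underlie the ratios of Krad_2551 (11.6 and 24.3 RPKM, 1.00) and Krad_2552 (10.7 and 24.9 RPKM, 1.15). Both passed the filter of 17.4 RPKM through the irradiated value alone. A second run held a von Willebrand factor A domain protein of the CoxE family (Krad_2045, 4.44 and 66.9 RPKM) and an ATPase (Krad_2047, 7.42-fold). The ratio of Krad_2045 rests on a low wild-type value and was 12.5-fold with a pseudocount of 1 RPKM and 5.32-fold with 10 RPKM. A LysM peptidoglycan-binding protein (Krad_1507) was 10.7-fold, an ATP-dependent DNA helicase (Krad_4305) 8.43-fold, a short protein named as a glycerol-phosphate porter (Krad_1952) 7.27-fold and a zinc-binding alcohol dehydrogenase (Krad_1039) 7.04-fold higher. Krad_1039 overlaps the end of Krad_1040 on the opposite strand, which had a log2 ratio of 2.74, and whether strand was used in counting is not given in the sources used here. Above the lowest of these 12 genes stood 6 genes of unknown function.

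Oxidative stress genes stayed close to 0, with a median log2 ratio of 0.08 at percentile 93.4 and 15 of 16 members within 2-fold. Catalase (Krad_0815), which breaks down hydrogen peroxide, was the exception, at 56.8 RPKM in the wild-type and 188 RPKM in the irradiated library, 3.27-fold higher. Superoxide dismutase (Krad_3578) was abundant in both, at 3528 and 3917 RPKM. The alkyl hydroperoxide reductase genes had 436 and 454 RPKM (Krad_0628) and 656 and 431 RPKM (Krad_3757).

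Of the 12 chaperone and protease genes, 4 were at least 2-fold lower in the irradiated library and none was 2-fold higher. The DnaK chaperone (Krad_4233) had 506 RPKM in the wild-type and 195 RPKM in the irradiated library, its cofactor GrpE (Krad_4232) 2067 and 718 RPKM and the DnaJ domain protein (Krad_4231) 702 and 205 RPKM. These neighbouring genes and the MerR family regulator Krad_4230 lay in a run of 5 genes that were all 2-fold lower. The small heat shock protein Hsp20 (Krad_3103) had 10089 RPKM in the wild-type and 3365 RPKM in the irradiated library. The other members lay within 2-fold, including GroES (Krad_0735, log2 ratio -0.49), GroEL (Krad_3636, -0.34, and Krad_0736, -0.73) and the FtsH protease (Krad_0538, 0.68). The median of the list was -0.42 at percentile 1.88 of matched random lists, but at percentile 29.5 of random lists drawn without matching on expression level.

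Iron and iron-sulfur genes had a median log2 ratio of 0.65 at percentile 99.92, although no member reached 2-fold higher as deposited and 2 did relative to the median of all genes. SufB (Krad_2917), SufD (Krad_2916) and SufC (Krad_2915), which assemble iron-sulfur clusters, had log2 ratios of 0.88, 0.68 and 0.66, and a siderophore-interacting protein (Krad_4105) went from 4296 to 7588 RPKM. In the same list, a regulator of the ferric uptake family (Krad_4538) had 57.8 RPKM in the wild-type and 8.97 RPKM in the irradiated library, the lowest log2 ratio of all named genes (-2.56, and -1.84 with a pseudocount of 10 RPKM). With this member weighing in, the mean of the list was 0.15, at percentile 84.

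Carbon metabolism genes lay on both sides of 0 within 1 stretch of neighbouring loci. Glyceraldehyde-3-phosphate dehydrogenase (Krad_2931, log2 ratio -1.30), phosphoglycerate kinase (Krad_2930, -1.06) and triose-phosphate isomerase (Krad_2929, -1.41), enzymes of glycolysis, were at least 2-fold lower in the irradiated library, while transketolase (Krad_2922, 0.89), transaldolase (Krad_2923, 0.58) and 6-phosphogluconolactonase (Krad_2926, 0.89), enzymes of the pentose phosphate pathway, had positive ratios. Glycolysis genes elsewhere lay within 2-fold on both sides of 0. Pyruvate kinase (Krad_2959) and phosphopyruvate hydratase (Krad_1073) were at 0.03, a phosphoglycerate mutase (Krad_3699) at 0.50 and fructose-bisphosphate aldolase (Krad_4124) at -0.41. Pentose phosphate genes elsewhere went both ways, with negative ratios for glucose-6-phosphate dehydrogenase (Krad_1200, -0.78, and Krad_0133, -0.51) and ratios of 0.52 (Krad_0003), 0.21 (Krad_1524) and -0.81 (Krad_2146) for 6-phosphogluconate dehydrogenase. The list of both pathways had a median of 0.02 at percentile 90.2, with 3 of 23 members 2-fold lower and none higher as deposited, but 1 lower and 2 higher relative to the median of all genes (Krad_2922 and Krad_2926, both 1.20), and its other triose-phosphate isomerase gene (Krad_1917) was at -0.38. Relative to the median of all genes, the dehydrogenase (-0.99) and the kinase (-0.75) were within 2-fold and the isomerase Krad_2929 was at -1.10. Of the 5 sugar uptake genes, 3 were 2-fold lower, with a median of -1.06 at percentile 3.25, among them a sugar transport ATPase (Krad_2944, 96.2 and 40.6 RPKM) and a sugar ABC transporter (Krad_2946, 71.5 and 30.2 RPKM). Relative to the median of all genes none of these 3 was 2-fold lower (-0.91 for Krad_2944, -0.90 for Krad_2946 and -0.75 for Krad_2231), and without a filter on low values the list median was -0.48 at percentile 33.0; without matching on expression the list lay outside the central 95% of random lists, at percentile 1.16.

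**Figure D3:**
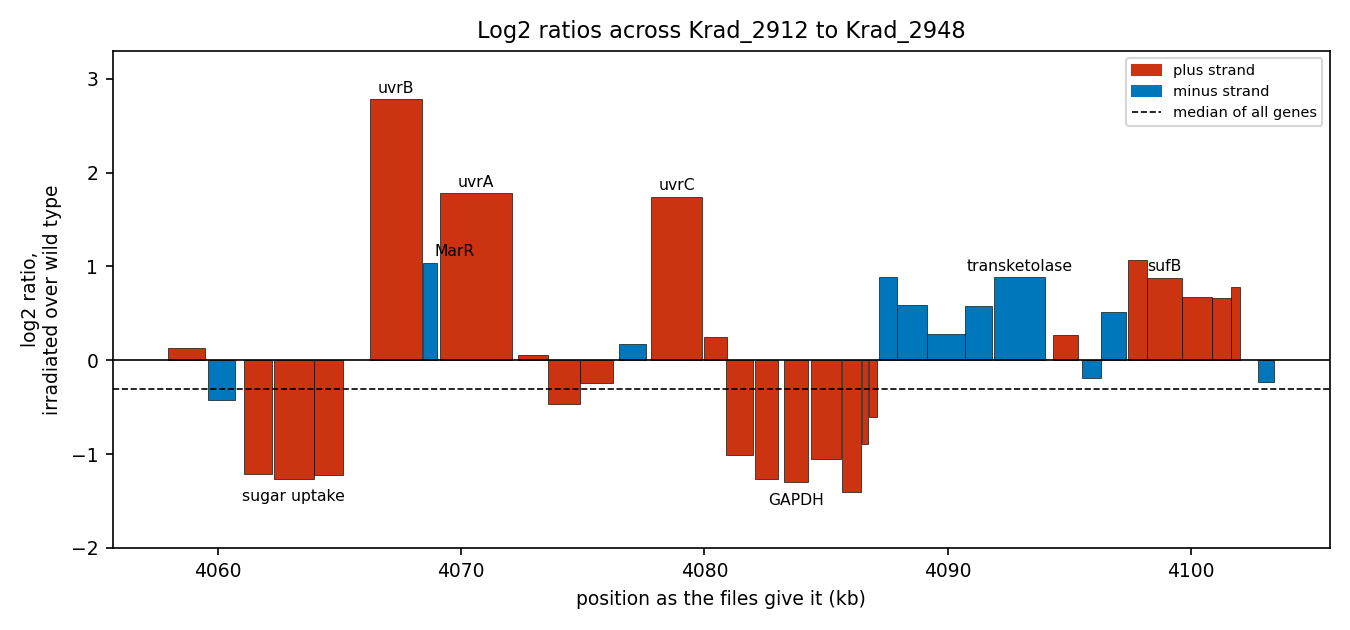
Log2 ratio of irradiated over wild type (y axis) for each gene listed in both libraries from Krad_2912 to Krad_2948, at its position in kb as the files give it (x axis), with strand by colour and the median of all genes (-0.31) dashed. The 3 excinuclease genes reach 1.78 (uvrA), 2.78 (uvrB) and 1.74 (uvrC), and the glycolysis genes and the sugar uptake genes on the same strand lie below -1.

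The lists of two-component systems and of transcriptional regulators had low medians. The median of sigma and anti-sigma factors was near that of all genes. Two-component systems, the sensor kinases and response regulators of signal transduction, had a median log2 ratio of -0.66 at percentile 0.53, with 8 of 38 members 2-fold lower and none higher. With a filter at the median expression the list came inside the central 95% of random lists (-0.50, percentile 11.985), and relative to the median of all genes 3 members were 2-fold lower. The list of transcriptional regulators, which shares 14 genes with the two-component list, had a median of -0.46 at percentile 0.3, with 25 of 136 members 2-fold lower and 5 higher, and 14 lower and 7 higher relative to the median of all genes. The 122 members not shared had a median of -0.44 at percentile 2.27, a split made after seeing the data. Among the lower ones were LuxR family response regulators, members of both lists (Krad_1992, -1.29, and Krad_2537, -1.03, which were -0.97 and -0.72 relative to the median of all genes), and a GntR family regulator (Krad_4399, 138 and 36.6 RPKM), and among the higher ones a WhiB-like regulator (Krad_4662), which went from 16.7 to 87.8 RPKM. Sigma and anti-sigma factors had a median of -0.35 at percentile 25.4, with 2 of 30 members higher and 1 lower; the sigma factor Krad_1151 was 3.29-fold higher and an anti-sigma factor (Krad_1570) had a log2 ratio of -1.25, or -0.94 relative to the median of all genes.

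The 12 named genes with the lowest ratios also included alanine racemase (Krad_0727, 85.5 and 17.9 RPKM), which makes D-alanine for the cell wall, a D-isomer specific dehydrogenase (Krad_1323, 46.2 and 10.8 RPKM), a phosphate transporter (Krad_0188, 69.5 and 16.6 RPKM), an extracellular solute-binding protein (Krad_0965, 78.3 and 19.8 RPKM), an AraC family regulator (Krad_2711, -1.82), a DoxX family protein (Krad_2652, -1.80), a kinase (Krad_2644, -1.76), an arabinofuranosidase (Krad_0962, -1.75) and a secreted protein next to the dnaK genes (Krad_4229, -1.74). The phosphate uptake genes Krad_0872, Krad_0873 and Krad_0875 formed another run of lower genes, with log2 ratios of -1.47, -1.40 and -1.71. Beyond the highest of these 12 genes stood 18 genes of unknown function.

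Genes of protein synthesis and energy supply differed little. All 34 ribosomal protein genes lay within 2-fold, with a median log2 ratio of -0.16 at percentile 7.49 of random lists matched on expression, 87.6 without matching and 41.99 when matched on protein length as well (a matching chosen after the data were seen), so its side depended on the matching. The 2 genes for ribosomal protein L33 had the largest ratios of that list, 0.77 (Krad_0663) and -0.72 (Krad_0286), and relative to the median of all genes Krad_0663 was 2-fold higher. All 16 genes of translation factors and aminoacyl-tRNA synthetases (median -0.05, percentile 75.3), all 14 genes of ATP synthase and the respiratory chain (-0.12, percentile 69.3), all 5 of the citric acid cycle (-0.05, percentile 69.9) and all 6 of RNA polymerase and termination (0.13, percentile 80.9) lay within 2-fold. Medians this close to 0 changed sign with the scaling. RNA polymerase subunit beta (Krad_0680) had 1216 RPKM in the wild-type and 1487 RPKM in the irradiated library. The lysyl-tRNA synthetase (Krad_0576) was at -0.55, elongation factor G (Krad_0684) at -0.39, the delta and A subunits of ATP synthase at -0.58 (Krad_1267) and -0.66 (Krad_1264), aconitase (Krad_1566) at -0.67 and NusG (Krad_0675) at 0.50.

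The remaining lists lay inside the central 95% of matched random lists. Carotenoid and isoprenoid synthesis had a median of 0.24 (percentile 94.8, 5 members), copper and heavy metals 0.02 (percentile 85.9, 5 members), cell division and cell wall -0.17 (percentile 59.2, 5 members), amino acid synthesis -0.18 (percentile 82.7, 34 members), amino acid and peptide uptake -0.47 (percentile 29.8, 6 members), flagella and chemotaxis -0.59 (percentile 8.64, or 50.6 with a filter at the median, 17 members) and mobile elements -0.36 (percentile 56.0, 9 members). The members of the carotenoid and isoprenoid list were general isoprenoid genes, such as geranylgeranyl reductase (Krad_0648, 68.9 and 81.7 RPKM), and none was named as a carotenoid enzyme. Within the others, 3-dehydroquinate dehydratase (Krad_1000) was 2.95-fold and a chemotaxis transducer (Krad_1002) 2.77-fold higher, and N-acetylglutamate synthase (Krad_0596, -1.51), a branched-chain amino acid transport protein (Krad_0205, -1.45) and CheW (Krad_0315, -1.52) were lower. The 3 universal stress proteins had log2 ratios of 1.26 (Krad_0069), 0.03 (Krad_2484) and -0.71 (Krad_1530), and the 4 genes of compatible solutes had a median of -0.43. No listed gene matched the ribosomal RNA or transfer RNA lists. In all, 4 of the 23 lists lay above and 3 below the central 95% of random lists. Lists share genes and hold neighbouring genes, whose ratios were correlated (r of 0.58 across same-strand pairs within 50 bp). More than 5% of lists can therefore fall outside by chance. In the simulation 7% of unchanged lists did. Its genes varied independently and its lists were drawn at random, so it does not measure the effect of shared or neighbouring genes.

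**Figure D4:**
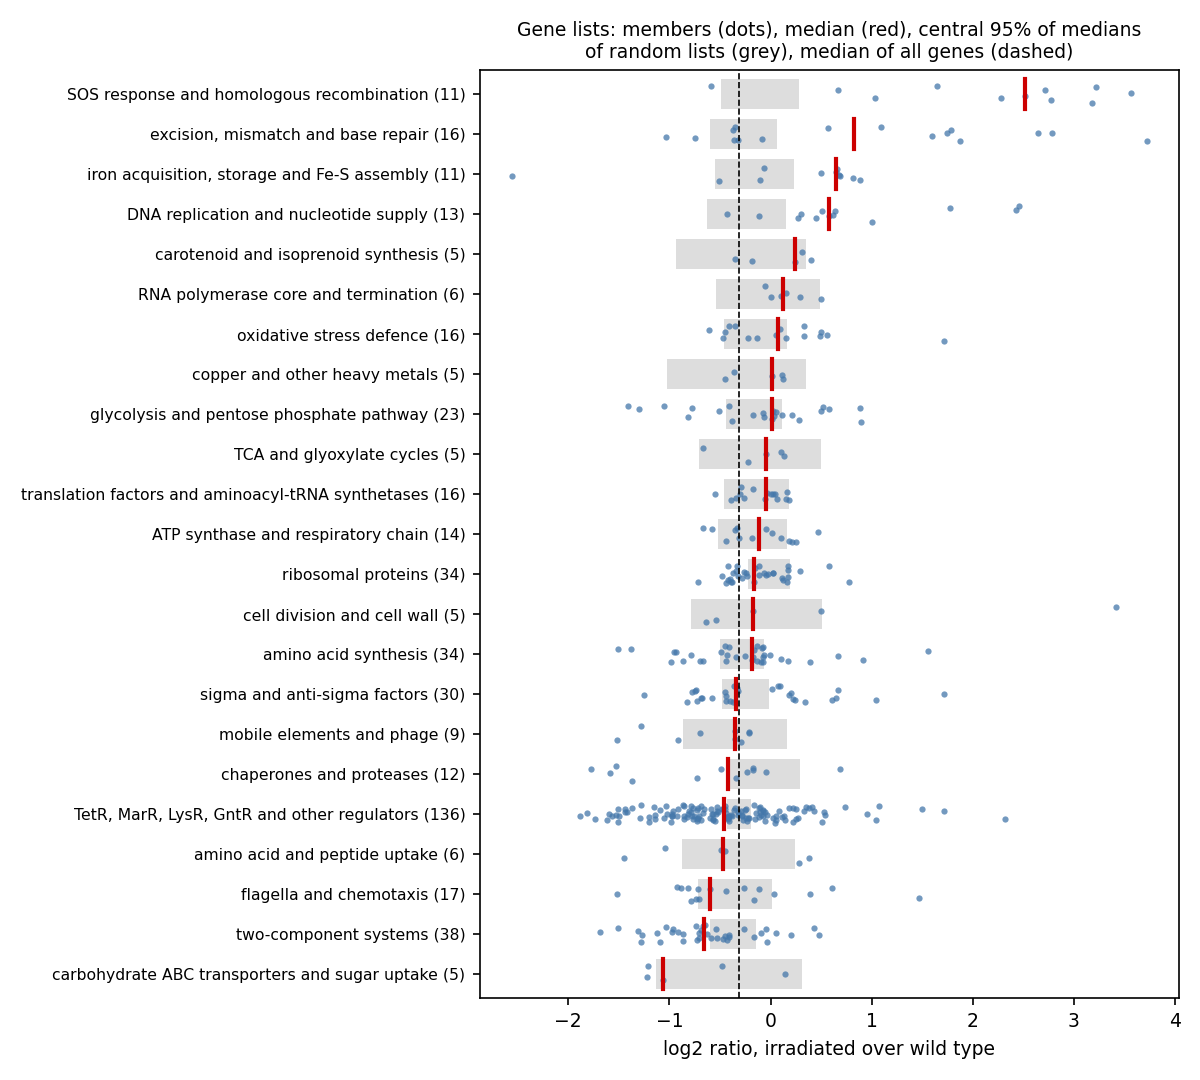
Log2 ratio of irradiated over wild type (x axis) for the members (dots) of each gene list with at least 5 members (y axis, number of members in brackets), with the list median in red, the central 95% of medians of 10000 matched random lists in grey and the median of all genes (-0.31) dashed. The recombination list has its median at 2.52, far to the right of its grey band, and two-component systems at -0.66, to the left of theirs.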

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

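The scalings were planned before the data were examined; their use on these genes, the test of protein length and the choice of the 4 heat-shock genes came after the results were seen. A total of 14 genes were listed in the irradiated library and not in the wild-type library, which brings them outside the comparison of ratios; the highest was Krad_0613, which encodes 32 amino acids of unknown function, at 282 RPKM. A gene for ribosomal protein L36 (Krad_0284, 40 amino acids) had 125 RPKM there. Another L36 gene (Krad_0712) was abundant in both libraries, at 21990 RPKM in the wild-type and 23834 RPKM in the irradiated one. In the other direction 25 genes were listed in the wild-type library alone, the highest being Krad_2399 (54 amino acids) at 157 RPKM. Of these 39 genes, 31 lay below the 25th percentile of all listed values, and the 5 above the median encode 95 amino acids or fewer. The lists hold only genes above 1 RPKM, so a missing gene is not shown to be silent, and no fold is given.

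The higher values of the recombination and SOS genes were set against scaling, protein length and a difference between single cultures. The tables argue against scaling, because the list's median stayed 2.83 above the median of all genes on the log2 scale, while the scalings tried moved every gene by 0.31 or less. Length is also argued against, because the median was 2.82 when each ratio was taken relative to the 100 genes nearest in length. With 1 library per group, a difference between the 2 cultures or preparations other than irradiation cannot be told apart from irradiation. A response to irradiation is the biological explanation the design names, and it stays open beside that one.

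The lower values of DnaK, GrpE, DnaJ and Hsp20 were picked out because they were low. Their median was 1.24 below that of all genes (-1.24), more than the scalings tried moved any gene. Genes chosen for low ratios had to lie below that median, so this distance does not decide about scaling. It shows only that the 4 genes stayed 2-fold lower after centring. Whether a loss was shared by the whole chaperone and protease list was not settled, because the 4 genes are its lowest members; 5 of the 12 members lay above the median of all genes. With 1 library per group, irradiation cannot be told apart from another difference between the cultures, and both stay open.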

How the results depend on the processing

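Added after seeing the data were entering genes missing from 1 library at 0, keeping the wrong list matches, matching random lists on length and removing from the regulator list the genes shared with two-component systems; none of these moved a count past 1.5 times or a list across the central 95%. Centring, also added for the runs of neighbouring genes, moved them from 3 higher and 9 lower to 8 higher and 2 lower. The median log2 ratio of all genes was -0.31 as deposited; scaling shifted every gene by 0.23 (upper quartile), -0.15 (total), -0.05 (total without the 50 most abundant genes) or 0.31 (centring). The cause of a difference was not tested unless the alternative itself gives it. Of 2-fold lower genes there were 152 with a pseudocount of 10, 159 with a filter at the median, which tests fewer genes, 161 with upper quartile scaling and 121 with centring, against 256; of 2-fold higher genes there were 194 with centring against 121. The 4-fold threshold, stricter by construction, left 47 higher and 19 lower. The other 13 of 20 counts stayed within 1.5 times. Pearson r across genes was 0.933 with a pseudocount of 10, 0.942 without a filter and 0.898 with a filter at the median.

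The medians stayed positive under every alternative run for recombination (2.37 to 2.83), excision repair (0.57 to 1.74) and replication (0.43 to 0.89). These lists also stayed above the central 95% of random lists, and their means, taken with no other setting changed, did so too. Centring and scaling shift all genes nearly alike, so they can hardly move a percentile and do not check a list's side. The list of 136 regulators (-0.61 to -0.15) stayed below the central 95%. Chaperones came inside it without a filter (-0.42, percentile 2.53) and without matching (-0.42, percentile 29.5), two-component systems with a filter at the median (-0.50, percentile 11.985), and iron genes by their mean (0.15, percentile 84). Without matching, oxidative stress (0.075, percentile 97.6), glycolysis and pentose phosphate (0.017, percentile 97.9) and sugar uptake (-1.06, percentile 1.16) went outside it. Lists inside the central range changed sign as follows. With centring, medians were 0.15 for ribosomal proteins, 0.26 for translation factors, 0.20 for ATP synthase and respiration, 0.27 for the citric acid cycle, 0.14 for cell division and 0.13 for amino acid synthesis, and with the upper quartile 0.069, 0.18, 0.11, 0.18, 0.057 and 0.046 in the same order. Scaled by the total, they were -0.075 for oxidative stress, -0.13 for glycolysis and pentose phosphate, -0.13 for copper and -0.027 for RNA polymerase; without the 50 most abundant genes, -0.031 for glycolysis and pentose phosphate and -0.029 for copper. Copper was -0.30 without a filter. The means were -0.12 for glycolysis and pentose phosphate, -0.11 for copper and 0.52 for cell division. The other 243 of 272 list values kept their sign and their side, the side being nearly fixed under centring and scaling. Of the 81 named genes, 10 crossed 2-fold under at least 1 of 8 alternatives, and none of those at least 2-fold apart changed sign. Depth is unknown, so what it limits could not be worked out.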

Other observations

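The COG classes given in the files, looked at after the lists, showed the same division. The class of replication, recombination and repair held 62 genes, of which 23 were at least 2-fold higher in the irradiated library and 3 lower, with a median log2 ratio of 0.53 at percentile 100 of matched random lists. Signal transduction (104 genes, median -0.53, percentile 0.21), transcription (170 genes, -0.42, percentile 1.71) and motility (18 genes, -0.68, percentile 2.35) lay at the low end. In the same order, 14, 25 and 1 of their genes were 2-fold lower and 4, 7 and 1 higher. Of all genes, 12.4% were 2-fold lower and 5.88% higher. The alternatives were not run for the classes. Carbohydrate genes had 31 of 144 members 2-fold lower and 3 higher, with a median of -0.40 at percentile 16.8. The classes share members with the lists and are not independent of them. In all, 20 classes and the group of genes with products of unknown function were computed.

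Runs of neighbouring genes at least 2-fold apart were more frequent than when the ratios were shuffled. Most of the 121 higher and 256 lower genes lay in no run. There were 12 runs of at least 3 neighbouring genes on the same strand with the same direction, 3 higher and 9 lower, with 43 genes in all, against a mean of 1.275 runs and at most 6 when the ratios were shuffled over the genes 1000 times. Relative to the median of all genes, an alternative added after seeing the data, there were 10 runs, 8 higher and 2 lower (mean of 0.609 and at most 4 when shuffled), so the balance of directions depended on the scaling; the lower runs were those of the phosphate uptake genes and of dnaK. Besides those already described, a run of higher genes held recR, and runs of lower genes as deposited held a xylose isomerase domain protein (Krad_0391, log2 ratio -1.17), a CMP/dCMP deaminase (Krad_2390, -1.55) and 6 genes of unknown function in runs of their own (Krad_2237 to Krad_2239, Krad_2841 to Krad_2843).

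Among genes that passed the filter, the median log2 ratio was -0.66 in the lowest of 10 groups by mean expression. It lay between -0.40 and -0.36 in groups 2 to 6, was -0.28 in group 7 and rose to 0.03 in the highest. The filter takes the larger of 2 values, so genes of low mean passed it through their higher library, which can shape the lowest group. Without a filter the median of all genes was -0.30, against -0.31 with it, so lower ratios at the lowest expression are not shown. Genes encoding fewer than 100 amino acids had a median of 301 RPKM in the wild-type and 215 RPKM in the irradiated library, against 46.8 and 37.2 RPKM for longer ones. The transposase genes Krad_2271 and Krad_2395 had identical values in both libraries, 36.2 and 28.1 RPKM, and are uncertain because they can share reads. Of the 81 named genes, 24 overlap a listed neighbour or meet it end to end within 50 bp.

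Why neighbouring genes had similar ratios was tested in 3 ways, the tests of converging genes and of distant genes being chosen after the correlations at several distances and orientations had been seen. Genes 10 places apart correlated with an r of 0.050 (across gene pairs), which argues against DNA or RNA content that differs over regions that long. At 5 places r was 0.10 (95% bootstrap interval over pairs 0.035 to 0.17). For same-strand genes 2 places and at least 300 bp apart it was 0.42, so shorter regions are not argued against. Neighbours on the same strand within 50 bp correlated with an r of 0.58 and neighbours on opposite strands with 0.47. The opposite-strand set pools converging and diverging pairs, which differed. Against the diverging pairs alone (0.30) the gap was wider, but that comparison was not planned. Shared transcripts were therefore not separated from other causes, and that explanation stays open. Among opposite-strand neighbours, pairs that converge had an r of 0.64 and pairs that diverge 0.30, a difference of 0.35 (95% bootstrap interval over pairs 0.15 to 0.58), as reads counted without regard to strand across the ends of converging genes could give. The end of the MarR family regulator Krad_2941 (log2 ratio 1.04), looked at after its values were seen, faces that of uvrB. It went from 568 to 1169 RPKM, a larger rise than that of uvrB (93.8 to 650 RPKM). Reads of uvrB counted across that end would therefore not account for all of its rise.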
